A study of Homo sapiens with 8 samples.

How the data were processed

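Total RNA of flash-frozen kidney cortex was hybridised to Affymetrix Human Transcriptome Array 2.0, 1 array per donor, with 4 donors in each of 2 groups, EDN and control. The groups and replicate numbers were taken from the sample titles. The design text of the series describes separate donors, so the spread within a group is between people, and nothing in the labels used here gives a scan date or batch. Details of single donors were not used, and XIST, TSIX and Y-linked genes were left out of every test because the samples come from people.

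The values analysed are the authors' deposited log2 expression values, 1 row per transcript cluster. RMA and Partek are named in the submitters' processing notes, without versions or roles. The log base was inferred here from the values, which ran from 2.11 to 19.93, the upper end being a ceiling at log2 of 1000000 that every array reached. How that ceiling arose is not given in the sources used here, so the step from intensity to log2 value is in part unknown and differences are given as log2 differences, not as exact folds. Between 44 and 55 rows per array were at the ceiling; 5 of the genes tested were there on all arrays and 7 on at least 1, and their differences are bounded by it. RMA corrects background, normalizes between arrays and summarises probes, which makes arrays alike in overall distribution; its settings are not given in the sources used here. The interquartile range still differed between the deposited arrays, so quantile normalization was tried as an alternative.

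Of 70523 rows, 23784 had 1 gene symbol in the platform annotation, 1540 had several and 45199 had none there. Rows with several or none were not named. The 1-symbol rows were given current symbols through the NCBI gene table of assembly GRCh38.p14: 21497 by Entrez number, 1977 by symbol, 306 by an older symbol, and 4 kept the annotation's symbol. For the 505 genes with over 1 row, the row with the highest mean over all 8 arrays was used, giving 22340 genes; no filter on dim genes was applied.

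EDN was compared with control in R 4.3.3 with limma 3.58.1: lmFit, then eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment over the 22340 genes and a threshold of adjusted p under 0.05. Differences are EDN minus control with the moderated standard error (median over genes 0.122). For C7 a two-sided exact permutation test of the difference of means was run over the 70 arrangements of 4 against 4, which cannot give a p below 0.0286. The code was tested on simulated data for this comparison with 22340 genes, of which 100 were shifted by 1 and 100 by 2 on the log2 scale: 72% and 96% were recovered at the adjusted threshold, with 15 unchanged genes called. The shifted genes were drawn at random, each with its own spread. These rates therefore do not carry over to more variable genes such as C7 (SE 0.93 against the median of 0.122). Of 10 simulated lists of 30 genes shifted by 0.4, 10 were called, and of 10 unshifted lists 0; the simulated genes varied independently, which real list members do not.

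Before the data were examined, 24 gene lists were fixed: complement system; extracellular matrix and fibrosis; injured tubule; proximal tubule; loop and distal tubule; collecting duct; podocyte; endothelium; mesangium, smooth muscle and fibroblast; lymphocyte and plasma cell; myeloid cell; chemokine and NF-kB inflammation; interferon response; immediate early and heat shock; hypoxia and glycolysis; nuclear oxidative phosphorylation; mitochondrial genome; fatty acid oxidation; gluconeogenesis and glucose handling; renin-angiotensin and vasoactive; blood; adipocyte; antioxidant NRF2 targets; and metallothionein. The mitochondrial genome list had 0 named genes here and was not tested, which left 23. Each list was tested against all other genes with camera at a preset correlation of 0.01, adjusted over the lists; camera with an estimated correlation and fry were alternatives. Camera compares the test statistics of a list's genes with those of all other genes, so its direction can differ from the sign of the list's mean difference. A list's score for a donor is the mean log2 value of its measured genes. An exact permutation test of these scores was added after the list results had been seen.

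Genes were named by a rule also fixed before the data were examined: C7; in each direction the 10 genes with the largest absolute log2 difference at the adjusted threshold, filled up with protein-coding genes at an unadjusted p under 0.01 whose groups did not overlap; and of each list up to 4 members with the smallest p and any member past the threshold adjusted over the list alone. Genes whose level can show an inherited variant, such as HLA genes, and immunoglobulin and T cell receptor segments were not eligible for the largest differences but stayed in the counts. As no gene passed the adjusted threshold, all 20 came from the filling rule, which had 92 eligible genes higher and 76 lower.

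Alternatives changed 1 choice at a time: a filter on dim genes, no intensity trend, a robust prior, quantile normalization, median centring, array weights, the mean of a gene's rows, all rows whether named or not (70155), the replicate number as a block, an unmoderated test, the immediate early or the proximal tubule list as a covariate, an adjusted p under 0.1, a fold of at least 1.5, and leaving out each donor in turn.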

Results

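Gene expression was measured in kidney cortex of 8 human donors, 4 with early diabetic nephropathy (EDN) and 4 without diabetes (control), with 1 Affymetrix Human Transcriptome Array 2.0 per donor. EDN is here a kidney disease of donors with type 2 diabetes, classed at the earlier stages from the pathology of the tissue. The comparison asks which transcripts differ between EDN and non-diabetic cortex. Obesity was more frequent in the EDN group per the series' design text, so the groups differ in more than diabetic kidney disease, and no test here separates these. The deposited log2 values ran from 2.11 to a ceiling of 19.93, and the array medians lay between 5.23 and 5.29. Each array's mean correlation with the other 7, across all rows of the value table, lay between 0.978 (control replicate 1) and 0.987 (EDN replicate 2). Outside the ceiling, no pair of arrays had more than 131 of 70523 values exactly equal as deposited, so no array was a copy of another. Precision is limited by the 4 arrays per group.

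Lists of matrix, stromal, immune cell and complement genes were higher in EDN cortex, and those of the proximal tubule and of the loop and distal tubule were lower. Of 23 gene lists tested, 7 were higher and 6 were lower in EDN at an adjusted p under 0.05 in limma's camera test with a preset correlation between genes of 0.01. These calls depend on the form of the test. With a correlation estimated from these arrays, 1 of the 13 lists passed, that of mesangium, smooth muscle and fibroblast. Its estimated correlation was 0.0099, close to the preset, yet its unadjusted camera p rose from 3.58e-08 to 0.00149. The preset value is thus not all that differs between these forms. For the matrix, myeloid and lymphocyte lists the estimated correlation was 0.33, 0.44 and 0.59. A p-value with the preset takes no account of how a list's genes vary together between donors. No single gene passed the adjusted threshold in limma, with 0 higher and 0 lower among 22340 genes and a smallest adjusted p of 0.834. At an unadjusted p under 0.05 there were 622 genes higher and 688 lower, 1310 in all where chance gives 1117. Of these, 47.5% were higher in the deposited values, against 63.0% after quantile normalization and 60.2% after centring each array on its median. The 4 donors of one group lay fully above or below the 4 of the other for 747 genes (3.34%, where chance gives 2.86%). Values for single genes below are therefore differences between these donors, none past the adjusted threshold.

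Smooth muscle and fibroblast genes gave the 1 list call that held with an estimated correlation. The list of mesangium, smooth muscle and fibroblast genes averaged 7.76 ± 0.17 in EDN and 7.20 ± 0.17 in control (mean log2 of its genes per donor, SD, n = 4 each), a difference of 0.56. All 4 EDN donors (7.66 to 8.02) lay above all 4 control donors (7.09 to 7.46). Of its 20 measured genes, 16 were higher and 4 lower, and 4 passed adjusted over the list alone, against 0 over all genes tested. Those 4 were TAGLN (transgelin, an actin-binding protein of smooth muscle; difference 1.51, SE 0.36), SYNPO2 (1.32, SE 0.33), ACTA2 (smooth muscle alpha-actin; 0.99, SE 0.26) and LMOD1 (leiomodin of smooth muscle; 0.83, SE 0.23). The list passed in camera at an adjusted p = 2.06e-07 and at an adjusted p = 0.0343 with an estimated correlation. In an exact permutation test of the donor scores the p was 0.0286, the smallest that 4 against 4 donors allow (70 arrangements, two-sided), and 0.438 adjusted over the lists.

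Genes of the extracellular matrix and fibrosis were higher almost throughout. The list's mean was 0.71 higher in EDN (8.75 ± 0.43 against 8.04 ± 0.32, SD, n = 4 each), with 30 of 31 measured genes higher, and 3 of the 4 EDN donors lay above the highest control. CCN2, connective tissue growth factor, was at 11.90 ± 0.40 in EDN and 10.25 ± 0.67 in control, a difference of 1.65 (SE 0.34), and was the 1 gene that passed adjusted over the list alone. LUM, the matrix proteoglycan lumican, differed by 2.06 (SE 0.69), COL6A2 by 0.35 (SE 0.10) and COL4A2, a chain of basement membrane collagen, by 0.33 (SE 0.11). Camera gave an adjusted p = 3.85e-16, and an adjusted p = 0.208 with an estimated correlation. The exact permutation p of the donor scores was 0.0571.

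Immune cell genes were higher in the mean with a wide spread between EDN donors. The myeloid list was 0.91 higher (8.32 ± 0.66 against 7.41 ± 0.36, SD, n = 4 each), with 18 of 19 genes higher and 0 past the threshold adjusted over the list alone. Its members with the smallest p were genes of tissue macrophages: VSIG4, a complement receptor, differed by 2.03 (SE 0.51), CD163, the haemoglobin scavenger receptor, by 2.96 (SE 0.90), the mannose receptor MRC1 by 1.92 (SE 0.68) and LYVE1 by 1.12 (SE 0.34). The list of lymphocyte and plasma cell genes was 0.57 higher (5.98 ± 0.60 against 5.41 ± 0.22), with 20 of 22 genes higher and 0 past adjusted over the list alone. JCHAIN, the joining chain of secreted antibodies, differed by 2.65 (SE 1.10), IL7R by 2.13 (SE 0.90), KLRB1 by 1.11 (SE 0.40) and CD3E by 0.56 (SE 0.23). In camera the adjusted p was 4.37e-10 for the myeloid and 1.86e-07 for the lymphocyte list, and with an estimated correlation the adjusted p was 0.307 and 0.471. Exact permutation of the donor scores gave p = 0.0571 and 0.143. The groups overlapped in both scores. EDN replicate 2 lay below control replicate 3 in the myeloid score (7.52 against 7.80). EDN replicates 2 and 3 lay below control replicate 3 in the lymphocyte score (5.57 and 5.47 against 5.61). Without EDN replicate 1, the highest EDN donor, the lymphocyte difference was 0.30 (adjusted p = 0.00089), and with the immediate early list as a covariate it was 0.19 and no longer passed (adjusted p = 0.176). JCHAIN differed by 1.62 and CD3E by 0.36 without EDN replicate 1.

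C7, a component of the terminal complement complex, is the transcript this study is known to have followed up. It was at 16.86 ± 0.59 in EDN and 14.12 ± 2.11 in control (log2, SD, n = 4 each), a difference of 2.74 (SE 0.93). The EDN donors lay at 17.64, 16.20, 16.73 and 16.89 and the control donors at 12.08, 14.58, 16.88 and 12.93, so that 1 control donor lay within the EDN range. The exact permutation test gave p = 0.0857 (70 arrangements, two-sided), which misses 0.05. Limma's p for this single gene was 0.0171 before adjustment, and its p adjusted over all genes was 0.850. Without control replicate 3 the difference was 3.67, with an exact p of 0.0286, the smallest possible there. That donor is the 1 control within the EDN range. Leaving it out separated the groups fully, so that p was fixed by the choice and is no support. With the proximal tubule list as a covariate the C7 difference was 1.46 in limma, and its unadjusted limma p was 0.183, no longer under 0.05.

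The complement list as a whole was 0.49 higher in EDN (8.09 ± 0.13 against 7.60 ± 0.31, SD, n = 4 each), with 20 of its 28 measured genes higher and a median difference of 0.16. Its members at the smallest p were in the early classical pathway as well as C7: the protease C1S differed by 1.32 (SE 0.36) and C1QA, a chain of the recognition molecule C1q, by 0.52 (SE 0.19), while C3AR1, a receptor on myeloid cells, differed by 1.04 (SE 0.29). None of its genes passed adjusted over the list alone. The list passed in camera at an adjusted p = 1.33e-04, with an adjusted p = 0.208 at an estimated correlation and an exact permutation p of 0.0857. With the proximal tubule list as a covariate its difference was 0.21 (adjusted p = 0.0377), and among the brighter genes alone it was 0.78.

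**Figure D1:**
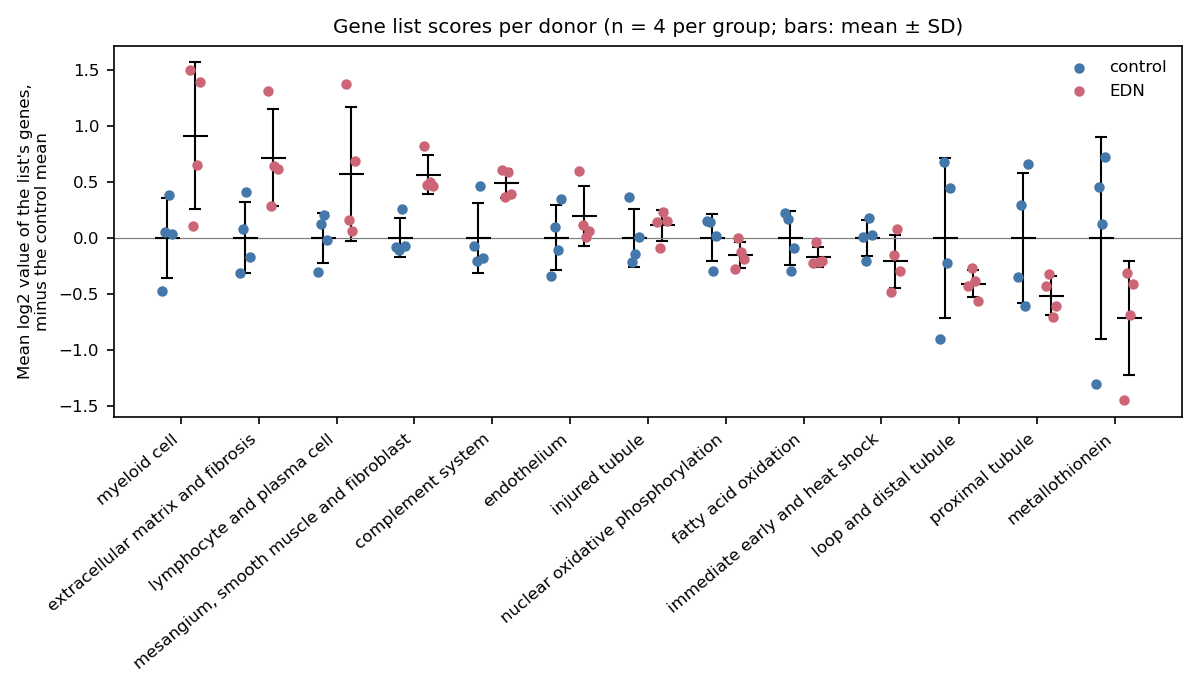
Mean log2 value of the genes of each list that passed camera with the preset correlation, per donor, after subtracting the control mean (y axis, log2), for 13 lists (x axis). Each point is 1 of 4 donors per group, and the horizontal line and bars are mean ± SD. The EDN points of the mesangium, smooth muscle and fibroblast list lie above all control points of that list.

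Transport genes of the proximal tubule were lower in EDN. The list fell by 0.52 in the mean (10.82 ± 0.17 against 11.34 ± 0.58, SD, n = 4 each), with 21 of 24 genes lower and 0 past adjusted over the list alone. The amino acid transporters SLC7A8 and SLC6A19 differed by -1.47 (SE 0.54) and -1.11 (SE 0.43), the organic anion transporter SLC22A8 by -1.13 (SE 0.48) and ANPEP, a brush border peptidase, by -0.92 (SE 0.39). Camera gave an adjusted p = 0.00244, with an adjusted p = 0.471 at an estimated correlation and an exact permutation p of 0.171. The control donors varied more than the EDN donors, and without control replicate 4 the difference was -0.30 and the camera adjusted p 0.125. Genes of the loop and distal tubule were 0.41 lower, with 14 of 16 genes lower, among them PTGER3 (prostaglandin receptor; -0.74, SE 0.27), KCNJ1 (-0.53, SE 0.26), CASR (-0.39, SE 0.25) and CALB1 (-0.74, SE 0.49). The adjusted p of that list was 0.0214 in camera and 0.643 with an estimated correlation, and its exact permutation p was 0.314. Its call was lost without EDN replicate 1 or 4 or control replicate 2 or 4, where the adjusted p reached 0.449, and in an unmoderated test (0.0701). Its difference ran from -0.19 without control replicate 2 to -0.71 without control replicate 1. With the proximal tubule list as a covariate the loop and distal difference was 0.01 (adjusted p = 0.877).

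Genes of energy metabolism were lower by small amounts. The fatty acid oxidation list was 0.17 lower, with 19 of 22 genes lower, among them PPARA, the transcription factor of fatty acid catabolism (-0.44, SE 0.18), ACADM (-0.49, SE 0.25), ECI2 (-0.34, SE 0.19) and ACOX2 (-0.46, SE 0.28). The nuclear oxidative phosphorylation list was 0.15 lower, with 24 of 28 genes lower and the respiratory complex I genes NDUFB10 (-0.30, SE 0.15), NDUFV1 (-0.33, SE 0.19), NDUFAB1 (-0.35, SE 0.21) and NDUFB3 (-0.40, SE 0.27) at its smallest p. Both lists were at an adjusted p = 0.0214 in camera, and with an estimated correlation at an adjusted p = 0.505 and 0.680. Exact permutation of their donor scores gave p = 0.257 and 0.286. Leaving out 1 donor ended the fatty acid call in 5 of 8 cases (EDN replicates 1, 3 and 4, control replicates 1 and 2), with an adjusted p of up to 0.296 and differences from -0.10 without control replicate 1 to -0.27 without control replicate 3. For oxidative phosphorylation it did so in 6 of 8 (the same 3 EDN donors, control replicates 1, 2 and 4), with up to 0.414 and differences from -0.10 without control replicate 1 to -0.25 without control replicate 3. With the proximal tubule list as a covariate the fatty acid difference was -0.05 (adjusted p = 0.877) and the oxidative phosphorylation difference was 0.00091 (adjusted p = 0.343).

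Metallothionein genes, which encode metal-binding proteins, were 0.72 lower, with 9 of 9 genes lower. MT2A was at 13.63 ± 0.43 in EDN and 14.38 ± 0.60 in control (SD, n = 4 each), and MT1E, MT1X and MT1H differed by -0.90 (SE 0.49), -1.0 (SE 0.56) and -1.42 (SE 0.93). These genes are close paralogs, so probes can be shared between them, and the 9 values are not 9 independent ones. The list passed in camera at an adjusted p = 0.00864, with an adjusted p = 0.505 at an estimated correlation and an exact permutation p of 0.229. It did not pass without EDN replicate 1, control replicate 2 or control replicate 4 (adjusted p up to 0.125), where the difference was as small as -0.47, nor with the proximal tubule list (-0.33, adjusted p = 0.295) or the immediate early list (-0.51, adjusted p = 0.179) as a covariate. Without control replicate 1 it was -1.15. Immediate early and heat shock genes were 0.21 lower, with 23 of 29 genes lower. Camera gave an adjusted p = 0.0402 and, with an estimated correlation, an adjusted p = 0.505, and the exact permutation p was 0.2. The small heat shock protein gene HSPB1 differed by -0.56 (SE 0.15), ATF3 by -0.33 (SE 0.16), EGR3 by -0.12 (SE 0.06) and JUNB by -0.53 (SE 0.27). That call was lost without EDN replicate 1 or 4 or control replicate 1, 3 or 4, with an adjusted p of up to 0.283 and a difference of -0.12 without EDN replicate 1, and with array weights (0.131) or an unmoderated test (0.101).

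Endothelial and injured tubule genes were slightly higher in the mean. The donor scores of the groups overlapped, with an exact permutation p of 0.371 for endothelium and 0.486 for injured tubule. The highest injured tubule score of all donors was that of control replicate 1 (10.84, against 10.38 to 10.71 in EDN). The endothelium list was 0.20 higher, with 13 of 18 genes higher, and VWF, von Willebrand factor, was its 1 gene past the threshold adjusted over the list alone (6.95 ± 0.27 against 6.28 ± 0.18, difference 0.67, SE 0.15, n = 4 each). PECAM1 differed by 0.70 (SE 0.36), CD34 by 0.81 (SE 0.45; 0.43 without EDN replicate 1) and ROBO4 by 0.18 (SE 0.09). Camera gave an adjusted p = 0.00449, with an adjusted p = 0.505 at an estimated correlation; the call was lost without EDN replicate 1 (difference 0.06, adjusted p = 0.217) or control replicate 1 (0.08, adjusted p = 0.145), with array weights (0.0935) and with the immediate early list as a covariate, where the difference was 0.01. Without control replicate 4 it was 0.31, and with the proximal tubule list as a covariate it was 0.39 (camera adjusted p = 1.02e-06). The injured tubule list was 0.11 higher, with 13 of 22 genes higher, at an adjusted p = 0.0214 and, with an estimated correlation, an adjusted p = 0.432. KRT19, a keratin of simple epithelia, differed by 0.56 (SE 0.21), PROM1 by 0.83 (SE 0.32), ANXA2 by 0.60 (SE 0.25) and IL34 by 0.26 (SE 0.11). The other 9 of the 22 genes were lower, among them SOX9 (-0.53, SE 0.36), HAVCR1 (-0.18, SE 0.94), LCN2 (-0.14, SE 0.16) and VCAM1 (-0.10, SE 0.55). SPP1, also counted there, was at the ceiling on 7 arrays and carries no information. This call was lost without EDN replicate 1 or 3 or control replicate 2 or 3 (adjusted p up to 0.141), with differences from 0.04 without control replicate 2 to 0.23 without control replicate 1, and with the proximal tubule list as a covariate (0.150).

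The remaining 10 lists did not pass. Collecting duct genes were 0.19 higher (adjusted p = 0.112 in camera; -0.04 without EDN replicate 2 or control replicate 1, and past the threshold without EDN replicate 4 or control replicate 2, at 0.28 and 0.41), with the sodium channel subunit SCNN1A at a difference of 0.71 (SE 0.28) and the water channel AQP2 at 1.93 (SE 1.12). Podocyte genes differed by -0.02 (adjusted p = 0.705; WT1 -0.31, SE 0.23), blood genes by -0.06 (0.534; HBB -0.30, SE 0.17), hypoxia and glycolysis genes by -0.06 (0.726; VEGFA -0.50, SE 0.28) and adipocyte genes by -0.03 (0.984; PLIN1 0.24, SE 0.11). Chemokine and NF-kB genes differed by -0.01 (adjusted p = 0.984), with NFKBIA at 0.50 (SE 0.19), and interferon response genes by -0.01 (0.984), with MX2 at 0.23 (SE 0.10) and IFIH1 at -0.31 (SE 0.12). Leaving out 1 donor, the interferon difference ran from -0.24 (without EDN replicate 1) to 0.16 (without control replicate 1). The sign of the chemokine and interferon means turned after quantile normalization and after median centring. Gluconeogenesis and glucose handling genes differed by -0.15 (adjusted p = 0.984), with TXNIP, a glucose-responsive gene, at 0.50 (SE 0.24). In the renin-angiotensin and vasoactive list (0.04, adjusted p = 0.952), EDNRB, an endothelin receptor, was at 12.93 ± 0.53 in EDN and 10.61 ± 1.74 in control (difference 2.33, SE 0.77, n = 4 each), AGTR1 differed by 0.63 (SE 0.25) and ACE by -0.31 (SE 0.13). Among antioxidant NRF2 targets (-0.05, adjusted p = 0.815), the cystine transporter SLC7A11 differed by 0.44 (SE 0.11) and was its 1 gene past the threshold adjusted over the list alone, and ABCC2 differed by -1.19 (SE 0.51). For the podocyte, NRF2, renin-angiotensin and interferon lists, the signs of the mean, the median and the camera test were not all the same. Leaving out control replicate 1 turned the gluconeogenesis difference to 0.07 and the hypoxia difference to 0.08. With 1 donor left out, the chemokine mean ran from -0.11 to 0.10, the renin-angiotensin mean from -0.06 to 0.12, the NRF2 mean from -0.27 to 0.16, the adipocyte mean from -0.07 to 0.02 and the blood mean from -0.09 to -0.03.

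The 10 genes given per direction had the largest differences among eligible protein-coding genes. Eligibility required an unadjusted p under 0.01 and groups that did not overlap. Larger differences outside this rule, such as those of CD163 and SLC7A8, are given above with their lists. The higher side was led by SVEP1, an extracellular matrix protein (9.42 ± 0.86 in EDN, 7.25 ± 0.88 in control; 2.18, SE 0.52), SPON1, the matrix protein spondin 1 (9.31 ± 0.57, 7.15 ± 0.99; 2.16, SE 0.49) and FHL5, a LIM domain protein (9.64 ± 1.07, 7.61 ± 0.36; 2.03, SE 0.48; SD, n = 4 each). MOXD1 followed at 1.85 (SE 0.55), ABCC9, a subunit of ATP-sensitive potassium channels, at 1.75 (SE 0.42), REG1A, a secreted lectin, at 1.69 (SE 0.27), CD69, a leukocyte activation marker, at 1.48 (SE 0.37) and CP, the copper carrier ceruloplasmin, at 1.41 (SE 0.30). CCN2 and TAGLN, given above with their lists, also belong to these 10. On the lower side PLG, plasminogen, stood apart, at 7.60 ± 0.73 in EDN and 9.60 ± 0.50 in control (SD, n = 4 each), a difference of -2.01 (SE 0.38). DIO1, a deiodinase that activates thyroid hormone, differed by -1.01 (SE 0.27), LPL, lipoprotein lipase, which is also in the adipocyte list, by -0.81 (SE 0.23), the kinase gene FRK by -0.71 (SE 0.17) and PAQR5 by -0.71 (SE 0.21). ZNF385D (-0.68, SE 0.10), SCD, stearoyl-CoA desaturase (-0.66, SE 0.18), HS6ST2 (-0.64, SE 0.16), CEP152 (-0.63, SE 0.16) and the olfactory receptor gene OR7D2 (-0.63, SE 0.18) completed the 10. For these 20 genes limma's adjusted p was 0.834.

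**Figure D2:**
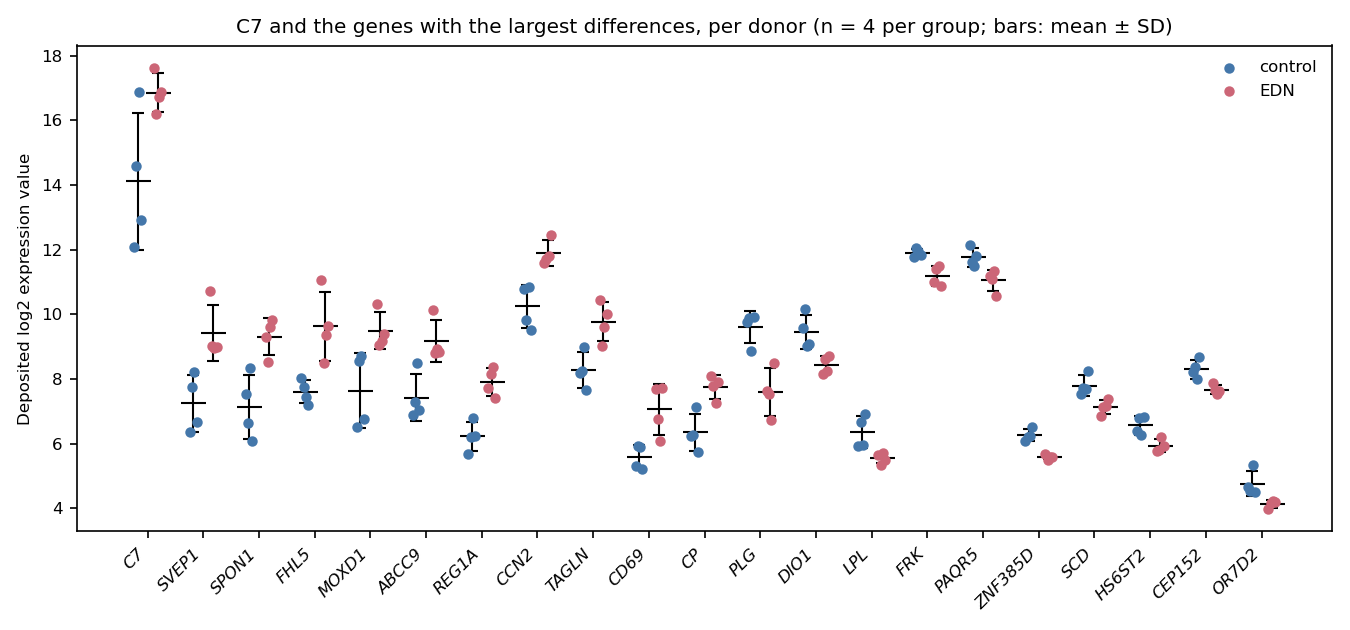
Deposited log2 expression (y axis) of C7 and 20 genes chosen by the naming rule (x axis), per donor. The 10 genes per direction had the largest differences among eligible protein-coding genes. Each point is 1 of 4 donors per group, and the horizontal line and bars are mean ± SD. Eligibility required an unadjusted p under 0.01 and groups that do not overlap. The separation of the 20 genes was thus fixed by their selection. C7 was not chosen by that rule, and 1 control donor, at 16.88, lies within its EDN range.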

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

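The test on the range of intensities was chosen only after array quartiles and principal components had been seen; the other 2 tests on the first component had their predictions written before their values were computed. In each group of 4 donors, an array was taken to stand apart when its gap to the nearest other array took a larger share of the group's range than Dixon's critical value for 4 samples. Among 268 groups, 18 had such an array, where chance gives about 13.4.

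EDN replicate 1 accounted for 7 of the 18. It was the highest EDN array for SVEP1 (10.7 against 8.95 to 9.03; gap 0.953 of the range), ABCC9 (10.1; 0.898), IL34 (6.29; 0.907), CD34 (9.59; 0.876) and FABP4 (6.87; 0.875), and for the list scores of mesangium, smooth muscle and fibroblast (8.02; 0.899) and interferon response (7.74; 0.879). Control replicate 3 was the lowest control array for PLG (8.86 against 9.76 to 9.91; 0.853) and the highest for OR7D2 (5.35; 0.841), AGTR1 (6.62; 0.834) and the mesangium, smooth muscle and fibroblast list (7.46; 0.909). EDN replicate 2 was the highest EDN array for PPARA (9.15; 0.908), the collecting duct list (9.95; 0.923) and the fatty acid oxidation list (9.67; 0.919). Control replicate 4 was highest for PPARA (9.69; 0.856), control replicate 2 lowest for EGR3 (3.56; 0.891), EDN replicate 3 highest for SELE (5.74; 0.907) and control replicate 1 highest for the gluconeogenesis list (10.1 against 9.16 to 9.22; 0.931).

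EDN replicate 1 and control replicate 1 also lay at the opposite ends of the first principal component over the genes tested, which held 34% of the variance and did not separate the groups (exact permutation p = 0.286). Over the 8 arrays the component correlated with the interquartile range of the array (r = -0.862, exact permutation p = 0.00794, adjusted over 3 relations 0.0183; rho = -0.738, p = 0.0458) and with the mean score of the lymphocyte and myeloid lists (r = -0.833, exact p = 0.0122, adjusted 0.0183; rho = -0.762, p = 0.0368). Without the 2 end arrays r was -0.55 (exact p = 0.272) and -0.34 (exact p = 0.543), so both relations rest on those arrays. For the loop and distal tubule and collecting duct lists minus the proximal tubule list, r was -0.493 (exact p = 0.267, adjusted 0.267; rho = -0.214, p = 0.619; without the ends -0.34, p = 0.553). This score was meant to follow medulla in the piece. It sets distal against proximal tubule genes and is not specific to medulla. A narrower range of intensities on control replicate 1 and more immune cells in EDN replicate 1 may each account for the component, and these values do not tell them apart. Control replicate 1 also had the highest injured tubule score of the 8 donors (10.84). Its loop and distal tubule (8.72), collecting duct (8.37), podocyte (8.19) and endothelium (7.73) scores were the lowest. Whether the state or make-up of that tissue accounts for the component was not tested.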

How the results depend on the processing

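All alternatives were planned before the data were examined, except the exact permutation test of list scores, chosen after the list results were seen. The counts of genes past the adjusted threshold were 0 in each direction under all 21 alternatives (smallest adjusted p 0.183, without control replicate 3). At unadjusted p under 0.05 the counts of genes higher and lower were 215 and 81 with a fold of at least 1.5, 353 and 274 among the brighter genes and 1368 and 2363 over all rows. The share higher was 56.3% among the brighter genes and 36.7% over all rows against 47.5%; the cause was not tested. With the proximal tubule covariate 246 genes were higher and 2 lists lower. With an estimated correlation 1 list was higher and 0 lower, and with fry also 1 and 0, the stromal list in both cases; with the exact test 0 lists passed (smallest adjusted p 0.438).

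Leaving out each donor, the number of lists lower ran from 1 to 6 against 6: 1 without EDN replicate 1 or control replicate 4, 2 without EDN replicate 4 or control replicate 2, and 3 without control replicate 1. The matrix, stromal, myeloid, lymphocyte and complement lists passed camera in 8 of 8 such fits, the lymphocyte difference being 0.30 without EDN replicate 1. The podocyte list ran from -0.24 to 0.16, the latter without control replicate 3 (adjusted p = 0.0316; 0.0316 to 0.994 over its alternatives). The C7 difference ran from 2.07 (without control replicate 1) to 3.67 (without control replicate 3), and was 1.46 in limma with the proximal tubule covariate. That covariate left the proximal tubule list at 0.043, by construction, the loop list at 0.010 and the oxidative phosphorylation list at 0.00091; the immediate early covariate left its own list at 0.019, by construction, and the NRF2 list at 0.309 (adjusted p = 0.00534; 0.00534 to 0.994 over its alternatives); with the proximal tubule covariate the NRF2 list was at -0.44 and passed in the opposite direction (adjusted p = 0.0220). The collecting duct list passed in 4 of 22 alternatives (lowest adjusted p 0.0228) and the interferon list in 1 of 22, at -0.27 with the immediate early covariate (adjusted p = 0.0167). The cause of the other changes was not tested. Of 2025 values of the 108 other named genes under alternatives, 2018 kept their direction, and 0 passed the adjusted threshold. These genes were chosen in these same arrays by the smallest p of their list or by groups that did not overlap. That choice favours a kept direction, so the count is no independent support. Leaving out 1 donor also moved by over 1.5 times, without turning them, the differences of IL34, MX2, JUNB and MT1X (EDN replicate 1), CASR (EDN replicate 2), CALB1 (EDN replicate 3), NDUFB10, NDUFAB1, NDUFB3 and MT1E (control replicate 1), SLC6A19, KCNJ1, NDUFV1, ACADM, ECI2, ACOX2 and MT1H (control replicate 2), AQP2 and WT1 (control replicate 3), and SCNN1A, VEGFA and HBB (control replicate 4).

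The replicate numbers do not pair donors: same-numbered donors' deviations from their group means correlated at -0.30, -0.03, -0.23 and -0.18. With a replicate block, 451 genes were higher and 513 lower at unadjusted p under 0.05, 0 passed the adjusted threshold, and 8 lists were higher and 6 lower. The sources used here hold no background signal, so the limit that signal over background sets for dim genes was not assessed.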

Other observations

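The splits of the donors, the comparison of immune and stromal lists with other cell types, the comparison of C7 with the stromal list's shift, and the 5 lists of the next paragraph were chosen after the list results had been seen; the other tests had their predictions written before their values were computed.

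Of 5 further gene groups, lymphatic endothelium stood out. Its mean was 0.32 higher in EDN, with 6 of 9 genes higher: LYVE1 (also in the myeloid list) differed by 1.12 (SE 0.34), the chemokine CCL21 by 1.19 (SE 0.94), MMRN1 by 0.50 (SE 0.25) and RELN by 0.23 (SE 0.08), of which the last 3 were at 0.17, 0.31 and 0.15 without EDN replicate 1, while PROX1, the transcription factor of lymphatic identity, differed by -0.41 (SE 0.15). Camera gave an adjusted p = 0.0277 over the 5 lists, with an adjusted p = 0.246 at an estimated correlation, and the exact permutation p was 0.0286, or 0.143 adjusted. Mast cell genes differed by 0.23 (adjusted p = 0.270; CPA3 1.33, SE 0.82, and 0.73 without EDN replicate 1), sterol synthesis genes by 0.13 (0.151), cytosolic ribosome genes by 0.02 (0.270) and proliferation genes by -0.05 (0.576). The hypothesis that gene groups outside the fixed lists also differ had 0 of 5 lists past the threshold with an estimated correlation. That had been written down as the outcome that would speak against it, but a missed threshold with 4 donors per group excludes no difference of the size seen here, so the hypothesis stays open.

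For the matrix, stromal, immune and complement lists, chance was not excluded: 5 of the 35 splits of the 8 donors into 4 and 4 put all 5 lists past the camera threshold in the same direction (the real 5, the highest other 5), and 3 of the other 4 place control replicate 3 with 3 EDN donors. Over all lists in both directions, 2 of the 35 splits gave as many past the threshold, the real 13 and a highest other of 13, in the split that exchanges EDN replicate 3 and control replicate 3. The array of control replicate 1, the least like the others, does not alone account for the pattern, since without it the differences of the 5 lists were 0.855 of those with all arrays (median; 0.820 to 0.952). EDN replicate 1 was not put to this test. Without it the matrix difference was 0.51 against 0.71 and the stromal 0.48 against 0.56. The myeloid difference was 0.72 against 0.91 and the lymphocyte difference 0.30 against 0.57, so that array carries part of the pattern. A lower share of tubule cells could raise all other cell types alike. The matrix, stromal and immune lists were higher by 0.569 more than the podocyte, endothelium and collecting duct lists (exact permutation p = 0.0857). This does not decide it, also because the collecting duct is itself a tubule segment. With the proximal tubule list as a covariate the matrix, stromal, lymphocyte and myeloid lists were still 0.48, 0.43, 0.49 and 0.68 higher. All 4 passed camera with the preset correlation (adjusted p up to 9.76e-06). There the endothelium and collecting duct lists were each at 0.39 and the podocyte list at -0.10. Diabetic kidney disease, the larger number of obese donors in the EDN group and unrecorded differences in tissue handling stay open as untested.

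For C7, 3 of the 35 splits gave a difference as large (2.74 for the real one, 3.09 for the highest other), so chance was not excluded. More stromal cells may account for the higher C7. With the stromal list as a covariate the C7 difference was 0.148 of its value, at 0.41 (SE 2.53), below the bound of 0.5 written beforehand; the list itself separates the groups fully, so the standard error exceeds the difference and the bound was judged uninformative after the value was seen. C7 exceeded the stromal list's shift by 2.18 (exact permutation p = 0.114). After removing group means, C7 and the stromal list correlated at r = 0.734 (exact p = 0.0521 over 576 arrangements; rho = 0.333, p = 0.549). The correlation was -0.52 (exact p = 0.333) without the 2 donors most extreme in the stromal list, EDN replicate 1 and control replicate 3. Stromal content and a change within cells therefore cannot be told apart.

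With a real count of 0 genes at adjusted p under 0.05, all 35 splits give as many by construction (highest other 1), so this count tests nothing. At unadjusted p under 0.05, 9 of the 35 splits gave as many genes as the real 1310 (highest other 2503, in the split of EDN replicates 1 and 2 with control replicates 3 and 4). The latter count does not exclude chance, and the larger counts of other splits point to differences between donors that do not follow the groups.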
